A study of Homo sapiens with 6 samples.

How the data were processed

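The series holds 6 arrays of the established human neuroblastoma line SH-SY5Y, 3 transfected with a GFP vector and 3 with a vector carrying dominant-negative TRF2. Per the labels' protocols, RNA was collected on day 7 after transfection from 3 independent experiments, and about 5 µg of total RNA was labelled with a radioactive nucleotide and hybridized in 1 channel to a cDNA array of 9600 spots. The values are linear intensity values per spot as the authors deposited them. The image software, background treatment and any scaling are not given in the sources used here. Deposited array medians were not equal, and no value was negative.

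The value 10.00 recurred on every array and was read as a stand-in for spots without signal. It filled nearly all of 384 positions, each 25th spot, of which 0 carried a gene name. These blank positions and 47 further spots at 10.00 on all 6 arrays were left out, which left 9169 spots. On each array between 1.51% and 2.48% of those lay at or under 10. Because the blanks hold this stand-in, signal over background cannot be measured exactly.

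Spots were named through the platform annotation, with symbols updated by gene ID to the current gene table (assembly GRCh38.p14), in which 8493 of 8517 annotated spots matched. Of the spots tested, 8451 had 1 gene symbol, 21 had several and were not named, and 697 had no listed gene here. The named spots covered 6255 genes, 1481 of them with at least 2 spots. Signal level was not a reliable measure of a gene's level between spots: over those 1481 genes the mean signal of the first and last spot correlated at 0.138, and over 131 clone accessions spotted more than once at -0.0360. Spots of ribosomal protein, tubulin, actin, GAPDH and EEF1A1 genes lay above the median signal in 92.7% of cases, against 48.0% of other named spots. Levels were therefore compared between arrays within a spot only. The differences at the first and last spot shared a sign in 51.0% of the 1481 genes. Such a share also arises where few spots truly differ, so it cannot show whether the annotation is right. The annotation may still be wrong for some spots, and a value given for a named gene is that of the spot so annotated. Clones of gene families such as tubulins, histones and ribosomal proteins can hybridize with RNA of related genes.

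An offset of 50 was added, log2 was taken and the arrays were quantile-normalized. The offset was set after the spread within groups had been compared at offsets of 1, 10, 25, 50 and 100, which gave median residual SDs of 0.25, 0.24, 0.23, 0.21 and 0.19, and before the groups were tested. Fold changes are on this offset scale, which understates changes of dim spots. Each spot was tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors given beside differences are standard errors from this fit. For lists, spots of one gene were averaged, and lists with at least 5 measured genes were tested with limma's camera at the preset correlation of 0.01, adjusted over 24 lists. Camera with an estimated correlation and fry were run beside it; fry tests a list against no change and does not compare it with other genes. A list's shift is the mean difference of its genes minus that of all other genes. Where members are adjusted over the list alone, the Benjamini-Hochberg adjustment covered that list's genes only. It was not corrected over the 24 lists. For each list the median was also set against 10000 random lists matched on mean signal in 20 bins.

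The lists, the tests of spots and of lists, and the first set of alternatives were fixed before the data were examined; alternatives and tests added later are named as such. Also fixed was the rule for named genes: the shelterin genes and REST; per direction 12 named genes of largest change among those that passed, with open places filled by the smallest unadjusted p among spots of above-median signal whose groups do not overlap; and up to 4 members of smallest p per list. As 0 spots passed, all places were filled by the second part of the rule, and the text names some of these genes. A gene with several spots was represented by the spot of smallest p, or of smallest p among the spots that the second part of the rule admits, which favours large differences, and the sign at its other spots is given where they disagree. CELA3B and the tubulin group were chosen after their values were seen.

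Replicate numbers 1 to 3 occur in both groups. Deviations from the group mean correlated between same-numbered arrays at 0.390, 0.296 and 0.246, and in these deviations all 6 arrays were closest to the array of their own number in the other group, so the numbers were taken to pair the samples. In the array values themselves this did not hold: DN-TRF2 replicates 1 and 2 correlated more with GFP control replicate 3 (0.987 and 0.986) than with the control of their own number (0.984 and 0.973). The pairing comes from these values; the labels name 3 experiments without tying a number to one. The unpaired fit had been fixed as the main one, and the fit with the replicate block is given where it changes a call or a count. The p-values of the unpaired fit measure the spread between samples within a group, including any part shared by same-numbered samples. Those of the block fit measure how the group difference varies between replicate numbers. Both include the noise of single arrays.

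Alternatives covered normalization, dim spots, the offset, variance moderation, array weights, the replicate block, each array left out in turn, and the handling of several spots per gene. Several were added after seeing the data. One sets values under 10 to 10, and another counts genes in place of spots. A position correction subtracts, on each array, the median deviation of neighbouring spots of other genes within 2 columns, 2 rows and 1 grid; the layout of 16 grids of 25 columns by 24 rows was inferred from the blanks and from correlations along the spot order. In all 12 versions of this correction were run, 2 of which gave no result because 7 spots had no neighbour. The version kept had the highest correlation between spots of one gene (0.156, against 0.132 for the lowest), and counts of calls under each version had been seen when it was chosen. The tests of spot position and of spots of one gene were also added later.

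The procedure was tested on simulated data over 9169 spots, 50 changed at each of 4 sizes. The data took this comparison's means and limma's moderated variances, which vary less between spots than the unmoderated ones. Limma recovered 10% of spots changed by 0.5, 80% at 1, and 100% at 1.5 and at 2 (log2), and called 16 unchanged spots. The simulated noise was independent between spots. A simulated shift of -0.20 in the mitosis list was fitted as -0.24 over 6255 genes, with 0 other lists called.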

Results

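RNA abundance was measured in SH-SY5Y cells, a human neuroblastoma line that keeps features of immature sympathetic neurons, 7 days after transfection and selection in geneticin at 500 µg/ml. The 3 GFP control samples carried a GFP vector with no insert. The 3 DN-TRF2 samples carried a dominant-negative form of TRF2, a protein that binds telomeric DNA as part of the shelterin complex. Each sample was hybridized as radiolabelled cDNA to 1 array of 9600 cDNA spots, and median intensity over the 9169 spots tested ran from 480 to 712 on the 6 arrays. The number of arrays limits the precision: the typical half-width of a difference at 1 spot was 0.47 on the log2 scale. This multiplies limma's standard error by the 95% t value for the residual degrees of freedom alone. It is therefore wider than the 95% interval that belongs to limma's own test, which adds prior degrees of freedom. Per the labels the groups also carried different plasmid backbones, which was not checked further, so that the insert and the backbone could not be separated. The series title concerns derepression of the neuronal programme when TRF2 is inhibited, and the comparison of the groups asks which genes differ with the dominant-negative protein.

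TRF2 itself (TERF2) and the neuronal repressor REST were not analysed here because no spot carried either name, and the labels could therefore not be checked against the targeted gene. Of the other shelterin genes, TERF2IP, which encodes the TRF2-binding protein RAP1, differed by 0.25 ± 0.16 (SE, log2 of DN-TRF2 over GFP control, n = 3 arrays per group) at 1 spot and by -0.25 ± 0.19 at its other spot. TINF2, which encodes the protein that links TRF1 to TRF2, differed by 0.18 ± 0.25 at 1 spot and -0.071 ± 0.22 at the other. The differences of ACD and POT1, which encode the partners that cap the single-stranded telomere end, were 0.0060 ± 0.15 and -0.0084 ± 0.27. None passed limma's test, with adjusted p of 0.999 for TERF2IP and TINF2 and 1.00 for ACD and POT1 over all spots, and 0 of the 14 measured genes of the shelterin and telomere maintenance list passed when adjusted over the list alone. The 14 include RAP1A (0.30 ± 0.14), a small GTPase gene that is not the telomeric RAP1 and does not belong in the list.

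Genes of mitosis were lower in DN-TRF2 cells as a group. Of 36 measured members, 28 had a lower mean, and the list fell by 0.13 (log2) relative to all other genes. On the 3 DN-TRF2 arrays the list lay at -0.079, -0.073 and -0.041 relative to other genes, below all 3 GFP control arrays at 0.053, 0.036 and 0.10. In arrays without pairing, chance alone separates 3 arrays from 3 in 10% of lists. The substrate-adherent list, given below, separated as well. CDK1, the kinase that drives entry into mitosis, differed by -0.33 ± 0.14 and ZWINT, a kinetochore protein, by -0.36 ± 0.15, with no overlap between the groups. Each has 1 spot, and both spots were dim, at mean signals of 7.42 and 7.36 (log2) against 9.12 over the list. The lack of overlap carries little weight, as it occurred at 8.70% of all spots. Against the list's direction, 1 of the 2 spots of UBE2C, the ubiquitin carrier of the anaphase-promoting complex, differed by 0.36 ± 0.17. The shift passed limma's camera test with its preset correlation (adjusted p = 0.000444 over 24 lists), but not with an estimated correlation (adjusted p = 0.183 with an estimated correlation). Fry, which tests the list against no change and not against other genes, gave adjusted p = 0.0693. No single member passed, either over all genes or adjusted over the list alone (0 of 36). The camera adjusted p was 0.0714 without GFP control replicate 3, at a shift of -0.11, and 0.0558 without the spots below median signal, at a shift of -0.12.

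Genes listed for substrate-adherent, mesenchymal-type neuroblastoma cells and stroma rose relative to other genes by 0.12 (log2), with a higher mean for 23 of 31 measured members and a median at percentile 99.5 of 10000 random lists matched on signal. TIMP1, a secreted inhibitor of matrix metalloproteinases, was higher by 0.77 ± 0.18 at 1 spot, and both of its spots were higher. S100A6, a calcium-binding protein, was higher by 0.66 ± 0.13, again at both of its spots. The caveolin gene CAV2 was higher by 0.48 ± 0.16 and the proteoglycan gene LUM by 0.45 ± 0.20. The TIMP1 and S100A6 spots were dim, at mean signals of 7.87 and 8.25 (log2) against 9.46 over the list. Those of CAV2 and LUM lay at 10.8 and 9.78. TIMP1 and S100A6 passed limma's test when adjusted over the list alone (adjusted p = 0.0202 for each, spots averaged per gene). That adjustment does not cover the other lists tested, and 0 members passed over all genes. The list had a camera adjusted p of 0.00913, and adjusted p = 0.508 with an estimated correlation; fry's test against no change gave 0.324. The call was lost without GFP control replicate 1 (shift 0.086, camera adjusted p = 0.221) and without GFP control replicate 3 (0.14, 0.0714). It was also lost without the spots below median signal (0.047, 0.620) and with the spot of highest signal per gene (0.099, 0.0903).

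The senescence secretome and lysosome list rose by a mean of 0.12 relative to other genes, while its median difference was 0.034, at percentile 87.3 of 10000 random lists matched on signal. Means were higher for 16 of its 27 measured members and 6 of those had an unadjusted p under 0.05. CTSL and CTSA, which encode lysosomal cathepsins, were higher by 0.52 ± 0.14 and 0.47 ± 0.17. CDKN1A, which encodes the cell-cycle inhibitor p21 and was also listed among p53 targets, was higher by 0.61 ± 0.14 at 1 spot and in the same direction at all 3 of its spots. Mean signals at the spots of CTSL, CTSA and TIMP1 were 8.78, 8.13 and 7.87 (log2), against 9.05 over the list. The CDKN1A spot lay at 10.1. TIMP1 and CTSL passed when adjusted over the list alone (limma adjusted p = 0.0268 and 0.0354), without adjustment over the other lists tested. Over all genes 0 members passed. The camera adjusted p was 0.0240, with adjusted p = 0.508 with an estimated correlation, and fry's test against no change gave 0.605. The call was lost without GFP control replicate 2 (shift 0.061, camera adjusted p = 0.412), without GFP control replicate 3 (0.13, 0.159) and without DN-TRF2 replicate 1 (0.092, 0.166). It was also lost without the spots below median signal (0.026, 0.847), without the quartile of dimmest spots (0.089, 0.118), with array weights (0.087, 0.0937) and with the spot of highest signal per gene (0.097, 0.0903). TIMP1 was the 1 gene measured in both this list and the substrate-adherent list.

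Cytosolic ribosomal protein genes fell by 0.13 relative to other genes, with lower means for 48 of 58 members. RPS6, a protein of the small subunit, differed by -0.40 ± 0.17 and was lower at all 3 of its spots, and RPL6 of the large subunit differed by -0.35 ± 0.18. Against them, RPL13 was higher at 6 of its 8 spots, by 0.37 ± 0.15 at the spot of smallest p. The list lay highest on 1 control array, at 0.39 on GFP control replicate 2, against -0.21 and 0.012 on the other control arrays and -0.16, -0.0087 and -0.019 on the DN-TRF2 arrays. Without GFP control replicate 2 the direction turned, with a shift of 0.035 (adjusted p = 0.547); it was -0.27 without GFP control replicate 1 and -0.078 without DN-TRF2 replicate 1. The camera adjusted p with all arrays was 0.00224, with adjusted p = 0.755 with an estimated correlation. The call was also lost without GFP control replicate 3 (-0.15, 0.0714), without DN-TRF2 replicate 1 (0.166) and with array weights (-0.042, 0.297), and fry's test against no change gave 0.851. No member passed adjusted over the list alone (0 of 58).

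**Figure D1:**
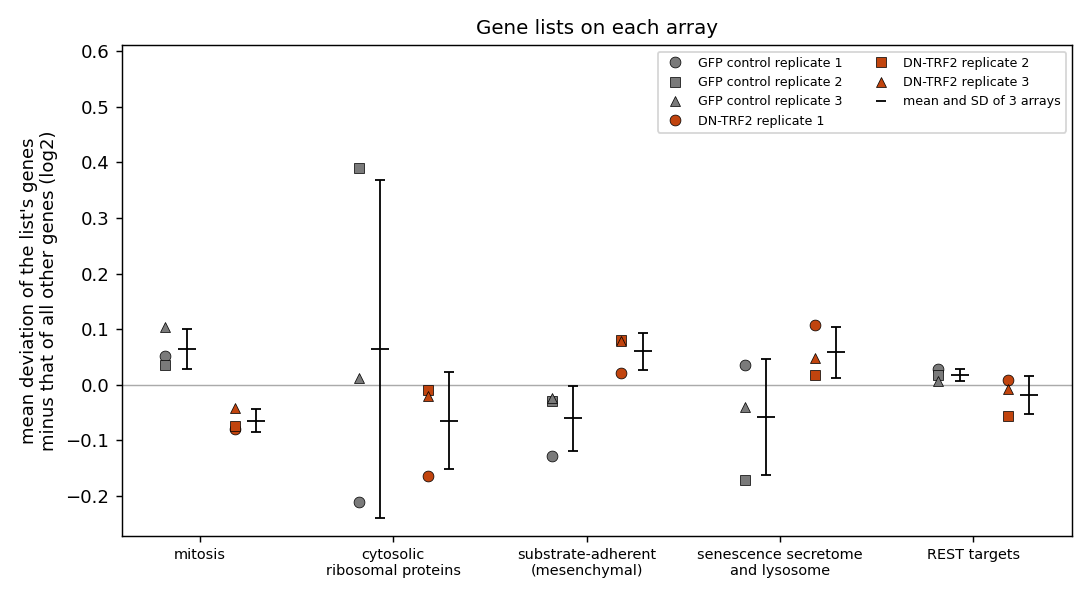
Mean deviation (log2) of each list's genes from their 6-array mean, minus that of all other genes, on each of the 6 arrays, for the 4 lists that passed camera at its preset correlation, of which 0 passed with an estimated correlation, and for the REST targets; bars give the mean and SD of 3 arrays. The mitosis list lies below 0 on all 3 DN-TRF2 arrays and above 0 on all 3 GFP control arrays, and the substrate-adherent list lies the other way round. The ribosomal protein list lies at 0.39 on GFP control replicate 2 alone.

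Neuronal genes that REST represses gave no shift that passed the test. Of 102 listed REST targets only 31 were measured. Of these 31, 13 had a higher and 18 a lower mean in DN-TRF2 cells, with a median difference of -0.068 (log2) at percentile 4.26 of 10000 random lists matched on signal. Members went both ways. The neuropeptide gene VIP was higher by 0.46 ± 0.14, and STX1A, a syntaxin of the synaptic release machinery, was higher by 0.57 ± 0.19 and at both of its spots. RAB3A, a GTPase of synaptic vesicles, differed by -0.55 ± 0.18, and TUBB3, the neuronal beta-tubulin, by -0.57 ± 0.20 with both spots lower. The list's shift of -0.036 had an adjusted p of 0.795 by limma's camera (0.772 with an estimated correlation), and 0 members passed adjusted over the list alone. At each replicate number the list lay lower on the DN-TRF2 array than on the control array, and with the replicate block its camera adjusted p was 0.619. The shift turned to 0.0040 after a correction for position on the array.

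The other neuronal lists gave no call with all arrays and spots. They are not separate evidence, since the synaptic list shares 10 measured genes with the REST targets and the cytoskeleton list 6. The neuronal cytoskeleton and neurite growth list had a camera adjusted p of 0.571, with 12 of 30 members higher: GAP43, a growth cone protein, differed by 0.46 ± 0.18 and TUBA1B, an alpha-tubulin, by -0.56 ± 0.20, with 1 of its 13 spots higher. Synaptic vesicle and exocytosis genes had 11 of 25 members higher (adjusted p = 0.590) and sympathoadrenal identity genes 7 of 14 (0.953). Within the latter, the transcription factor gene GATA3 was higher at all 3 of its spots, by 0.45 ± 0.15 at the spot of smallest p, and the spots of the granule protein gene CHGA disagreed in sign. Neural progenitor genes had 9 of 14 members higher (0.391), with SOX9, a progenitor transcription factor, at 0.33 ± 0.13. Their shift of 0.060 came to 0.14 without the quartile of dimmest spots, where the list was called higher (camera adjusted p = 0.0464, 10 genes measured). It was 0.13 without the spots below median signal, where the list was not called (0.218). With 1 array left out it ran, uncalled, from 0.037 without GFP control replicate 2 to 0.093 without GFP control replicate 1. In each of these lists 0 members passed limma's test over all genes or adjusted over the list alone.

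Growth, damage and stress lists were not called either. DNA replication genes had 19 of 36 members higher (camera adjusted p = 0.874), although the helicase subunit gene MCM7 differed by -0.81 ± 0.23 with both spots lower and the replication licensing inhibitor gene GMNN by -0.37 ± 0.15. The p53 target list had 11 of 25 members higher (0.834), among them CDKN1A and the death receptor gene TNFRSF10B at 0.44 ± 0.17. DNA damage response genes had 14 of 27 higher (0.874), REST complex and degradation genes 8 of 15 (0.980), shelterin and telomere maintenance genes, with RAP1A counted, 7 of 14 (0.874), proteasome genes 19 of 35 (0.874), and heat shock and unfolded protein genes 13 of 36 (0.391). Interferon response genes had 15 of 25 higher (0.571) and apoptosis genes 14 of 27 (0.571). Median, mean and camera direction differed in sign for the p53 target, shelterin, REST complex, DNA replication, proteasome and sympathoadrenal lists. Adjusted over the list alone, 0 members of any of these lists passed.

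Metabolic lists and markers of other cell types gave no call by camera with all arrays at equal weight. Oxidative phosphorylation genes had 28 of 61 members higher (adjusted p = 0.874), glycolysis genes 2 of 14 (0.391), cholesterol and fatty acid synthesis genes 13 of 22 (0.874) and mRNA splicing and export genes 15 of 44 (0.571). The glycolysis shift of -0.083 was called lower with array weights (-0.13, camera adjusted p = 0.0329) and without GFP control replicate 2 (-0.19, 0.00640), and was -0.012 without GFP control replicate 1 (0.995) and -0.015 without DN-TRF2 replicate 2 (0.884). The oxidative phosphorylation shift of -0.0088 turned to 0.095 without GFP control replicate 2, where the list was called higher (0.0141), and was -0.091 without GFP control replicate 1 (0.0715) and 0.041 with array weights (0.345). Blood and immune cell markers had 9 of 17 members higher and liver and epithelial markers 13 of 25, each with an adjusted p of 0.571. Adjusted over the list alone, 0 members passed in each.

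Across all 9169 spots, 0 passed limma's test at an adjusted p under 0.05 in either direction, the smallest being 0.999. An unadjusted p under 0.05 was found at 212 spots higher and 101 lower in DN-TRF2, 313 in all, against 458 that chance would give in arrays without pairing. With the replicate number as a block 336 were higher and 191 lower, 527 in all, and 0 passed (smallest adjusted p 0.269); a test without moderated variance also called 0, with 387 at an unadjusted p under 0.05. The 313 came to 786 without GFP control replicate 2, 653 without GFP control replicate 3, 140 without DN-TRF2 replicate 2 and 155 without DN-TRF2 replicate 3, and 0 passed in each. The groups did not overlap at 8.70% of spots, where chance gives 10% in arrays without pairing, and the samples here appear paired by replicate number. Among the higher spots of smallest p with above-median signal were FAM209B (1.09 ± 0.24), NCALD, a neuronal calcium sensor (0.75 ± 0.18), PTN, a secreted neurite growth factor (0.60 ± 0.15), TFPI2, a secreted protease inhibitor (0.76 ± 0.20) and PPARD, a nuclear receptor (0.66 ± 0.19). The remaining places went to PLD4 (0.69 ± 0.16), the pancreatic lipase relative PNLIPRP1 (0.84 ± 0.20), CDKN1A, NCK2, DHX58, COX10 and OTUB2. COX10 and OTUB2 were each higher at 1 of 2 spots. On the lower side were NAPA, a protein of membrane fusion (-0.45 ± 0.14), SERPINF1, a secreted factor (-0.42 ± 0.14), SMOX, a polyamine oxidase (-0.42 ± 0.16) and CYCS, cytochrome c (-0.43 ± 0.17, with a smaller p at a dimmer spot, -0.47 ± 0.15, and higher at 3 of its 14 spots). None of these genes passed (limma adjusted p = 0.999 for each).

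GFP control arrays were more spread than DN-TRF2 arrays, with a median SD per spot of 0.24 against 0.13 (log2) and the larger SD in the controls at 78.0% of spots. Correlations between arrays, taken across spots, ran from 0.954 to 0.980 among controls and from 0.987 to 0.992 among DN-TRF2 arrays, and from 0.966 to 0.992 between the groups. GFP control replicate 2 deviated most from its group, with an SD over spots of 0.30 against 0.25 and 0.21 for control replicates 1 and 3. It correlated with them at 0.954 and 0.963. Replicates 1 and 3 correlated with each other at 0.980, still below every DN-TRF2 pair.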

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

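Alternatives added after seeing the data were the position corrections, the floor at 10, the counts by gene, and camera with an estimated correlation in the fits with the replicate block or position correction. Throughout, 0 spots passed limma's adjusted p in either direction, with 1 exception. With position correction and replicate block together, 8 of the 10 versions that gave a result called 1 higher spot, CELA3B (pancreatic elastase), and 2 versions, the one kept among them, called 0; the smallest adjusted p ran from 0.0103 to 0.0710 and spots at an unadjusted p under 0.05 from 658 to 809. Without the block all 10 called 0. CELA3B differed by 0.98 ± 0.20, at an adjusted p of 0.999 without correction or block.

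Spots at an unadjusted p under 0.05, 212 higher and 101 lower, came to 336 and 191 with the replicate block, 65 and 16 without normalization, 91 and 24 without the spots below median signal (fewer spots tested), and 364 and 301 with position correction and block. The lower count alone moved to 52 without the quartile of dimmest spots, 273 with array weights, 183 without moderation and 152 with the floor at 10. At a threshold of 0.01 they were 39 and 12. Leaving out 1 array gave 101 to 484 higher and 39 to 391 lower. Beyond these 2 counts, the block changed no call in the preset tests.

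Of the lists called, 2 higher and 2 lower, 0 were called in either direction with an estimated correlation, at unmoved shifts: adjusted p for mitosis, ribosomal, substrate-adherent and senescence lists were 0.183, 0.755, 0.508 and 0.508. Fry, which tests mean differences (-0.13, -0.12, 0.12 and 0.12) against no change, called 0 in either direction (0.0693, 0.851, 0.324 and 0.605). An estimated correlation gave 0.720 for all 4 with the block (shifts -0.13, -0.13, 0.12 and 0.12). With position correction the shifts were -0.10, -0.13, 0.12 and 0.13, at 0.222, 0.821, 0.295 and 0.222 with an estimated correlation, and 0.510, 0.806, 0.510 and 0.510 with the block added. The preset test kept all 4 with position correction. Without the spots below median signal 0 higher lists and 1 lower list were called (substrate-adherent 0.047, adjusted p 0.620; mitosis -0.12, 0.0558; senescence 0.026, 0.847), and without the quartile of dimmest spots senescence was lost (0.089, 0.118) and neural progenitor gained (0.14, 0.0464). Array weights left 1 higher list, losing ribosomal (-0.042, 0.297) and senescence (0.087, 0.0937) and gaining glycolysis as lower (-0.13, 0.0329). The spot of highest signal per gene left 0 higher lists (substrate-adherent 0.099 and senescence 0.097, both at 0.0903). Leaving out 1 array, 0 to 2 higher and 0 to 2 lower lists were called, with shifts of -0.14 to -0.11 (mitosis), -0.27 to 0.035 (ribosomal), 0.086 to 0.14 (substrate-adherent), 0.061 to 0.16 (senescence), -0.19 to -0.012 (glycolysis), 0.037 to 0.093 (neural progenitor) and -0.091 to 0.095 (oxidative phosphorylation). Without GFP control replicate 2 glycolysis was called lower (-0.19, 0.00640) and oxidative phosphorylation higher (0.095, 0.0141). The oxidative phosphorylation shift of -0.0088 also turned, uncalled, to 0.041 with array weights, 0.011 without DN-TRF2 replicate 1 and 0.0039 with position correction, with or without the block or an estimated correlation. The cause was not tested, apart from the settings that test fewer spots or arrays.

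The REST target shift of -0.036 turned to 0.0040 with position correction, with or without the block or an estimated correlation, and was not called under any setting. Among 111 named genes and 2321 alternative values, 15 had the opposite sign, all of differences that passed no test. POT1 was 0.015 with median centring, 0.0056 as a z-score, 0.069 without normalization, 0.00034 with cyclic loess and 0.11 with position correction (also with the block), and -0.36 to 0.21 with 1 array left out. TINF2 was -0.048 with array weights and -0.14 to 0.35 with 1 array left out, and ACD -0.074 to 0.081.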

Other observations

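Tests of spot position and of spots of one gene, and the tubulin group, were chosen only after results had been seen. The alpha- and beta-tubulin genes, which encode the subunits of microtubules, did not form a list of their own, though some belong to the neuronal cytoskeleton, mitosis or REST target lists. Of 12 measured members 11 had lower means in DN-TRF2, as did 37 of their 40 spots, with a median difference of -0.34 (log2); TUBB2B was the exception, and under the alternatives 9 to 12 members had lower means, 9 of them without GFP control replicate 3. Their shift was -0.31, with an unadjusted camera p of 4.31e-05 and p = 0.233 with an estimated correlation, on a group picked for its values; with the replicate block the p were 3.88e-08 and 0.145. Relative to other genes the group lay at 0.44, -0.46 and 0.49 on the 3 control arrays and at 0.10, -0.50 and -0.072 on the DN-TRF2 arrays, lower in DN-TRF2 at each replicate number and lowest on replicate 2 in each group. The shift was -0.15 without GFP control replicate 3, -0.17 without GFP control replicate 1, -0.14 without DN-TRF2 replicate 2 and -0.62 without GFP control replicate 2. The unadjusted p of limma's camera was 0.125 in the fit without GFP control replicate 3.

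EEF1A1, an elongation factor of translation, was higher at all 9 of its spots in DN-TRF2 (0.17 ± 0.15, spots averaged), while RPL3, a ribosomal protein of the large subunit, was higher at 2 of its 11 (-0.10 ± 0.13). The cathepsin gene CTSB differed by 0.49 ± 0.18 and the chemokine gene CCL2 by 0.35 ± 0.13. None passed limma's test, and these genes were chosen after their values were seen.

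The mitosis list was lower in DN-TRF2. After subtracting the neighbours' deviation its shift was -0.10 (preset camera adjusted p = 0.000476, but 0.222 with an estimated correlation and 0.510 with the block added). That correction was partial, since group differences of spots 25 apart in the spot order still correlated at 0.290, against 0.464 before. Position on the array is therefore not excluded. A bias that depends on signal did not account for the shift, since the list's median lay below all 10000 random lists of matched signal, at percentile 0. No single array carried it alone: over the 6 fits without 1 array the sign held and the highest unadjusted camera p was 0.00892, although the adjusted p without GFP control replicate 3 was 0.0714. Of the 10 splits of the arrays 2 called as many lists, 4 in the real split and at most 4 in the others, and so few splits give no share under 0.05. The other splits that part all 3 pairs called 0, 2 and 2. The mitosis shift itself was 0.13 in the real split, against at most 0.077 in the others. That order was fixed in advance, because the groups do not overlap for this list, so it says nothing further on chance. Correlation among these genes (p = 0.00762 unadjusted and 0.183 adjusted with it estimated), the plasmid backbone that differs per the labels, and slower proliferation with dominant-negative TRF2, a hypothesis not tested here and with a DNA replication list shift of -0.0096 (camera adjusted p = 0.874), may each account for the shift and stay open.

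The ribosomal protein list was lower too. Its shift was -0.13 after the position correction (preset camera adjusted p = 0.000476, but 0.821 with an estimated correlation and 0.806 with the block added). As that correction was partial, position is not excluded. Signal-dependent bias as a general trend did not account for the shift (percentile 0). A single array is a candidate explanation: the highest unadjusted camera p with 1 array left out was 0.296, without GFP control replicate 2, where the direction turned. That array had the lowest array weight, 0.241, and in the fit without it the shift was 0.035 (camera adjusted p = 0.547), against -0.042 (0.297) with array weights. Beyond GFP control replicate 2 these values give no support for a biological difference between the groups, which is not excluded. At replicate number 1 the list lay lower on the control array (-0.21) than on the DN-TRF2 array (-0.16). At number 3 the values were 0.012 and -0.019.

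Group differences were shared by neighbouring spots. Spots 25 apart in the spot order correlated at 0.464, above the 0.0281 that was the highest of 1000 random reorderings, and the correlation was 0.464 without pairs of one gene, which argues against genes spotted side by side. Position on the membrane is a candidate source, and the position correction removed only part of the correlation, which was then 0.290 for spots 25 apart. After a correction for position the differences at the first and last spot of 1481 genes correlated at 0.156, up from 0.0932 by 0.0623 (bootstrap 95% interval 0.026 to 0.10, for the version picked on this measure). They shared a sign in 54.0% of genes against 51.0% before. Shares this low also arise where few spots truly differ. That, position noise hiding gene-wise differences, and spots whose annotation is wrong all stay open. Spots at an unadjusted p under 0.05 came to as many in 6 of the 10 splits, 313 in the real split and 1000 in the highest other, which set GFP control replicates 1 and 3 with DN-TRF2 replicate 1 against the rest and points to a structure of the samples; the other splits that part all 3 pairs gave 185, 173 and 89.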
